A study of Mus musculus with 6 samples.

How the data were processed

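Splenic endothelial cells of 6 Apoe-knockout mice were profiled by bulk RNA sequencing, 1 library per mouse. Per the labels, 3 mice (1601, 1602 and 1608) had received a control antisense oligonucleotide (ASO) and 3 mice (1603, 1604 and 1607) an ASO against Mlkl, in both cases for 8 weeks together with a high cholesterol diet. Per the labels' protocols, RNA was extracted with the Direct-zol kit and libraries were made with a directional mRNA kit from New England BioLabs. How the endothelial cells were isolated is not given in the sources used here.

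Per the submitters' processing notes, the tools used were fastp 0.20.1, a read trimmer, Salmon 1.3.0, which assigns reads to transcripts by similarity and splits reads that match several, and DESeq2. The genome build and annotation are not given in the sources used here, so genes are named by symbol and no coordinates are printed. The deposited table of estimated counts has 23207 gene symbols, of which 4 are numbers and not names. Of its values, 69.3% are not whole numbers, as an estimate that splits reads between transcripts gives. Genes with near-identical copies are therefore uncertain. The authors also deposited a DESeq2 table of 54347 rows, whose columns, per the file headers, are a mean normalised count (a signal averaged over libraries), a log2 fold change and its standard error, a Wald score, and a p-value with its adjusted value. Of its rows, 31121 carry no gene symbol and 17 symbols stand on more than 1 row. Rows with such symbols or with none were left out when single genes were compared. The direction of the authors' log2 fold changes was settled from the data: across 19728 genes they correlated with those computed here for MLKL ASO minus control ASO at a Pearson r of 0.977, so positive values mean higher in MLKL ASO. Genes are not independent replicates, and both tables come from the same libraries.

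The estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by the default expression filter of edgeR, which left 19745, and libraries were scaled by TMM. The groups were compared with the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values, counts scaled to a common library total, were computed with the TMM-scaled totals, and values are given as mean ± SD over 3 mice. Mouse numbers do not recur between groups and the labels name no batch, so no block was fitted. With 3 mice against 3, the smallest p that an exact two-sided permutation test allows is 0.1.

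Before the data were examined, 39 gene lists with 755 distinct genes were fixed from textbook knowledge of endothelium, spleen, necroptosis, cholesterol feeding and cells that a spleen preparation can hold. They were tested with camera (limma 3.58.1), a competitive test that asks whether the genes of a list lie higher or lower than all other genes, with its preset correlation of 0.01 between genes and adjustment over the lists. Lists with fewer than 5 measured members were not tested, which left out the sex-linked list with 2 of 6 members measured and kept 38 lists. Camera with a correlation estimated from the data and fry, which tests whether a list's genes move on balance in a given direction without comparing them with other genes, were run beside it, the latter also with its mixed test for change in either direction. List levels per mouse are means of log2 CPM with a prior count of 2.

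The genes named in the text were set by a rule fixed before the data were examined. It takes Mlkl, then up to 12 genes per direction past the threshold with a mean of at least 1 CPM and groups that do not overlap, then up to 4 members with the smallest p from each list past the threshold, and 9 genes whatever their result (Ripk3, Ripk1, Pecam1, Cdh5, Stab2, Cxcl12, Kitl, Vcam1 and Apoe). Genes outside the rule are said to have been chosen after their values were seen. The values of 1 gene that the rule names are not reported here. Alternatives were other normalisations, count filters from none to at least 1 CPM in 3 libraries, robust fitting, DESeq2 1.42.0, limma-voom with sample weights, a covariate of haematopoietic marker levels, and leaving out each mouse. A likelihood-ratio test in edgeR, the removal of globin, immunoglobulin and T cell receptor genes, a covariate of erythroid marker levels and the lists without Mlkl were added after seeing the data.

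The tests were tested on simulated data, with counts drawn for the same 19745 genes from the means and totals of these libraries and 200 genes changed. The edgeR quasi-likelihood test recovered 11 of 100 genes changed 2-fold and 52 of 100 changed 4-fold, with 3 unchanged genes called. DESeq2 recovered 38 and 79 of these with 44 unchanged genes called, and limma-voom with sample weights 12 and 50 with 2 unchanged genes called. A simulated list of 25 genes shifted by 0.5 on the log2 scale had an adjusted p of 1.1e-09 in camera with the preset correlation and an adjusted p of 0.0558 with an estimated correlation, and 0 of the unchanged lists were called either way. In these simulations each gene was drawn independently, so the simulated lists held no correlation between their members. The unchanged lists therefore cannot show how often camera calls lists whose genes move together. Library totals lay between 59988846 and 87776706 estimated counts. The common biological coefficient of variation between mice of a group was 33.5%.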

Results

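RNA was sequenced from splenic endothelial cells of Apoe-knockout mice, which lack apolipoprotein E and become strongly hypercholesterolaemic on a cholesterol-rich diet. The mice had been treated for 8 weeks, while on that diet, with an antisense oligonucleotide (ASO, a short synthetic nucleic acid that pairs with a chosen RNA and lowers it) that was either a control or directed against Mlkl. Mlkl encodes the pseudokinase that ruptures the plasma membrane in necroptosis. Each group held 3 mice, numbers 1601, 1602 and 1608 with the control ASO and numbers 1603, 1604 and 1607 with the MLKL ASO. Per the title of the series, the question was how Mlkl in the spleen bears on blood formation during atherosclerosis. Library totals in the order of mouse number were 87776706, 81103235, 59988846, 68798389, 85724084 and 67699450 estimated counts.

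Libraries of the MLKL ASO group resembled each other more closely (Spearman correlation across genes 0.982 to 0.984) than those of the control group (0.962 to 0.977), and pairs from different groups reached 0.964 to 0.977. The first principal component of log2 CPM held 30.2% of the variance and set control mouse 1608 apart, with a coordinate of 92.0 against 16.3 or less in the other mice. The groups did not overlap on it: mice 1603, 1604 and 1607 lay at -27.87, -44.25 and -31.22, below control mice 1601 (-4.958) and 1602 (16.27). RNA of blood cells was present in every library. Globin genes took 4.77% of the counts in mouse 1608, 5.05% in mouse 1602 and 11.7% in mouse 1601 of the control group, and 8.30%, 15.1% and 7.17% in mice 1603, 1604 and 1607 of the MLKL ASO group. Immunoglobulin genes took 1.74% to 3.81% in control mice and 1.48% to 1.76% in MLKL ASO mice.

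Mlkl was lower in each mouse given the MLKL ASO. Its level was 33.3 ± 4.09 CPM (SD, n = 3) in control mice and 5.70 ± 1.90 CPM (SD, n = 3) in MLKL ASO mice, a 5.86-fold difference. The control mice 1601, 1602 and 1608 measured 30.7, 31.2 and 38.0 CPM, and mice 1603, 1604 and 1607 measured 7.53, 5.81 and 3.74 CPM, so the labels and the target gene go together in all 6 mice. The log2 fold change was -2.55 with a standard error of 0.27, and its adjusted p in edgeR's quasi-likelihood test over all genes, 0.0655, lay above the threshold. The exact two-sided permutation test of Mlkl gave p = 0.1, the smallest that 3 mice against 3 allow. DESeq2 placed the gene past the threshold (adjusted p = 2.07e-15), as did the authors' deposited table (log2 fold change -2.69, adjusted p = 2.84e-15).

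Past the threshold in edgeR, Ces2e rose and Cyp21a1 fell in MLKL ASO mice. Ces2e, a carboxylesterase that hydrolyses esters and amides, went from 7.39 ± 0.499 CPM (SD, n = 3) to 40.6 ± 5.12 CPM (SD, n = 3), a log2 fold change of 2.46 with a standard error of 0.15 (edgeR adjusted p = 0.0111). Cyp21a1, the steroid 21-hydroxylase, went from 96.7 ± 20 CPM (SD, n = 3) to 20.2 ± 0.765 CPM (SD, n = 3), a log2 fold change of -2.26 with a standard error of 0.17 (edgeR adjusted p = 0.0197). The pseudogene Cyp21a2-ps, named here after its values were seen, shares sequence with Cyp21a1, so the copy that the reads came from is uncertain. It measured 1.44 ± 0.568 CPM in control and 0.101 ± 0.152 CPM in MLKL ASO mice. As it was low in both groups and also lower with the MLKL ASO, a shift of reads between the copies is argued against as the source of the fall. Ces2e and Cyp21a1 were the 1 gene higher and 1 gene lower among 19745 tested, while 965 genes were higher and 1374 lower at an unadjusted p under 0.05. DESeq2 called 237 higher and 290 lower, and limma-voom with sample weights 9 and 13. The authors' deposited table has 197 rows higher and 211 lower past the same threshold. Of the 388 of these genes that were also tested here, 388 had the same sign in edgeR, and 380 of them also had an unadjusted p under 0.05. Groups did not overlap in 3699 genes, or 18.7%, where chance gives 10% as an average over the ways to split the mice. As many genes move together, single splits can lie far from that average. The share was not counted for the other splits, so an excess over chance was not tested. Both edgeR calls were lost without mouse 1602, 1603, 1604 or 1607 (0 higher and 0 lower each time), although in these runs of 5 mice the log2 fold change stayed at 2.38 to 2.55 for Ces2e and at -2.38 to -2.25 for Cyp21a1. There were 10 genes higher and 9 lower without mouse 1608, and 1 higher and 3 lower without mouse 1601.

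**Figure D1:**
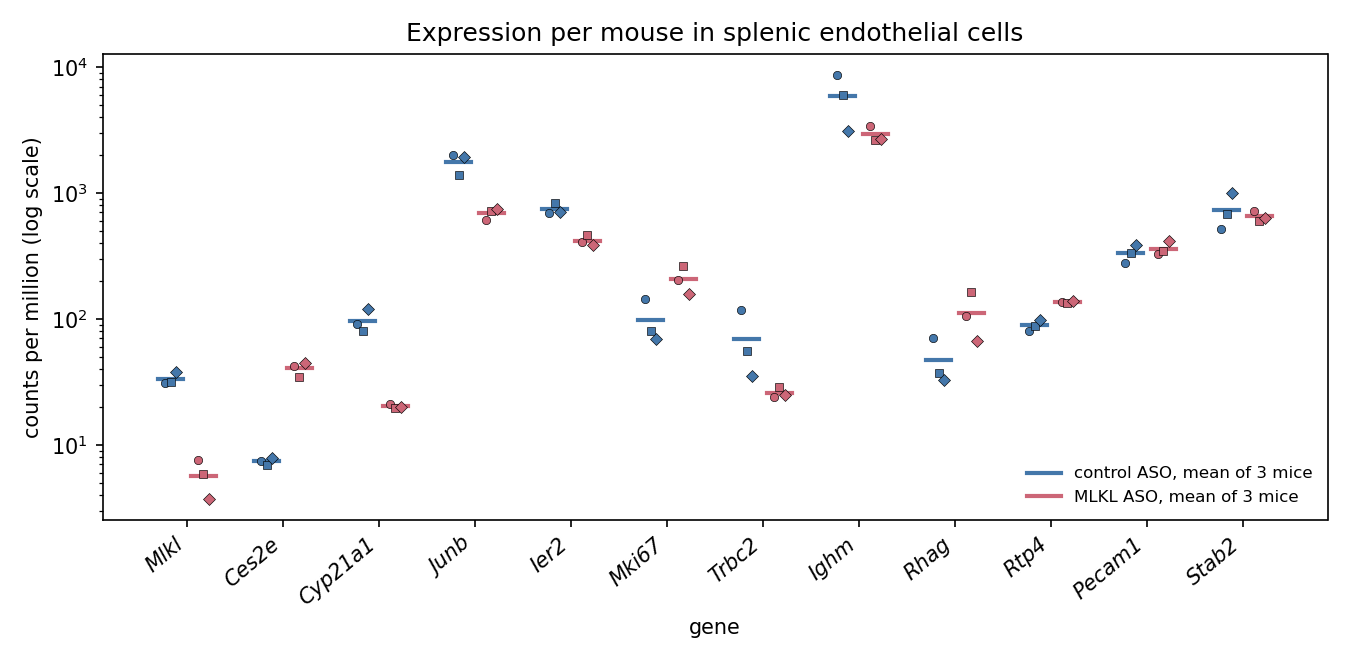
Expression per mouse in CPM on a log scale for 12 genes, with a point for each of 3 control ASO mice (blue) and 3 MLKL ASO mice (red) and a bar at each group mean. Mlkl lies at 30.7 CPM or more in the control mice and at 7.53 CPM or less in the MLKL ASO mice, and Ces2e and Cyp21a1 are likewise separated without overlap, whereas Pecam1 and Stab2 overlap between the groups.

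Of 38 gene lists tested with camera at its preset correlation, 6 were higher and 11 lower in MLKL ASO mice. With a correlation estimated from the data 0 lists passed (3 at an unadjusted p under 0.05), and by fry's directional test 0 passed (9 at an unadjusted p under 0.05). By fry's mixed test, which asks for change in either direction and does not compare a list with other genes, 8 lists passed, among them the unfolded protein response (fry adjusted p = 0.0118), LXR targets and lipid handling (fry adjusted p = 0.0259) and apoptosis (fry adjusted p = 0.0267), which did not pass camera. Of the 10 ways to split the 6 mice into 3 and 3, 4 gave at least 17 lists past the threshold at the preset correlation, the labelled grouping included. Within the lists, 0 members passed when adjusted over all genes tested, so values for members are given below without a call unless stated.

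Genes of proliferation were higher in MLKL ASO mice as a list. All 29 measured members of the cell cycle list had a log2 fold change above 0, with a median of 0.78 (camera adjusted p = 6.92e-16, but adjusted p = 0.427 with an estimated correlation), and 0 of them passed when adjusted over the list alone. Mki67, a nuclear marker of cycling cells, measured 98.1 ± 40.4 CPM in control and 208 ± 52.0 CPM in MLKL ASO mice. Tpx2, a spindle assembly factor, measured 38.1 ± 12.5 and 74.0 ± 9.60 CPM, Cenpf, a kinetochore protein, 26.7 ± 9.11 and 54.2 ± 10 CPM, and Ccne2, cyclin E2, 21.1 ± 8.38 and 45.9 ± 8.28 CPM. DESeq2 called 4 members of this list higher, as did the authors' deposited table. The median was 1.20 without mouse 1601.

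Markers of erythroid cells and megakaryocytes were higher as lists in the same mice. The erythroid list had 18 of 18 measured members above 0 and a median log2 fold change of 0.77 (camera adjusted p = 5.85e-07, but adjusted p = 0.525 with an estimated correlation), and 0 members passed when adjusted over the list alone. Rhag, a red cell membrane protein, measured 46.7 ± 20.7 CPM in control and 112 ± 48.4 CPM in MLKL ASO mice, and Tfrc, the transferrin receptor, 68.4 ± 29.3 and 131 ± 49.1 CPM. The erythroid median was 1.17 without mouse 1601, 0.44 without mouse 1604 and 0.46 without mouse 1608. All 12 megakaryocyte and platelet markers were above 0, with a median of 1.01 (camera adjusted p = 1.52e-05, but adjusted p = 0.525 with an estimated correlation), and 0 of them passed when adjusted over the list alone. Itgb3, the platelet integrin β3, measured 46.8 ± 19.8 and 84.1 ± 32.5 CPM, and Clec1b, the podoplanin receptor of platelets, 41.1 ± 22.2 and 72.7 ± 14.2 CPM. Mouse 1608 held the lowest megakaryocyte level of all libraries, and without it the median was 0.52. The list levels of control and MLKL ASO mice overlapped for cell cycle, erythroid, megakaryocyte, neutrophil and reticular fibroblast genes. Neutrophil genes had 15 of 17 members above 0 and a median of 0.47 (camera adjusted p = 0.0354, but adjusted p = 0.865 with an estimated correlation), among them Mpo, the granule enzyme myeloperoxidase, at 74.4 ± 69.5 and 173 ± 132 CPM, and 0 passed when adjusted over the list alone. That call held without mouse 1601 (median 1.83) or mouse 1603 (0.73), and was lost without mouse 1602 (0.16), mouse 1604 (-0.0069), mouse 1607 (0.46) or mouse 1608 (0.0092). Reticular fibroblast genes had 13 of 18 members above 0 and a median of 0.24 (camera adjusted p = 0.0473, but adjusted p = 0.825 with an estimated correlation), with 0 past the threshold when adjusted over the list alone. Lum, the matrix proteoglycan lumican, measured 0.375 ± 0.329 and 2.97 ± 0.582 CPM in this list, whose call was lost without mouse 1604 (median 0.089) or mouse 1608 (-0.23), while the median was 0.69 without mouse 1601 and 0.37 without mouse 1602.

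Lymphocyte markers were lower as lists in MLKL ASO mice. The T and NK cell list had 18 of 19 members below 0 and a median log2 fold change of -1.03 (camera adjusted p = 4.88e-13, but adjusted p = 0.427 with an estimated correlation). Adjusted over the list alone, 15 members passed as lower. Trbc2, a constant chain of the T cell receptor, measured 69.5 ± 43.0 CPM in control and 25.9 ± 2.63 CPM in MLKL ASO mice, and the coreceptor gene Cd4 26.2 ± 13.4 and 10.7 ± 1.61 CPM. The B cell list had 15 of 15 measured members below 0 and a median of -0.86 (camera adjusted p = 2.84e-08, but adjusted p = 0.427 with an estimated correlation), and the plasma cell list 9 of 9 and a median of -0.78 (camera adjusted p = 0.00158, but adjusted p = 0.427 with an estimated correlation). Neither had a member past the threshold when adjusted over the list alone (0 in each), and the levels of both lists overlapped between the groups (exact permutation p = 0.2, two-sided, n = 3 per group). Ighm, the heavy chain of IgM, measured 5895 ± 2760 and 2920 ± 441 CPM, and Jchain, the joining chain of secreted antibodies, 1731 ± 760.0 and 924 ± 148 CPM. Of 11 dendritic cell markers 10 were below 0, with a median of -0.53 (camera adjusted p = 0.00921, but adjusted p = 0.427 with an estimated correlation), and 0 passed when adjusted over the list alone. Among them Ccr7, the chemokine receptor that guides cells to T cell zones, measured 322 ± 141 and 171 ± 34.7 CPM. In the control group Trbc2 ranged from 34.9 CPM in mouse 1608 to 118 CPM in mouse 1601. Without mouse 1601 the medians were -0.63 for T and NK cell, -0.44 for B cell and -0.35 for plasma cell genes, all still past the threshold at the preset correlation, and -0.33 for dendritic cell genes, which no longer passed (camera adjusted p = 0.0826). The log2 fold change of Trbc2 was -1.42 with all mice and -0.82 without mouse 1601.

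**Figure D2:**
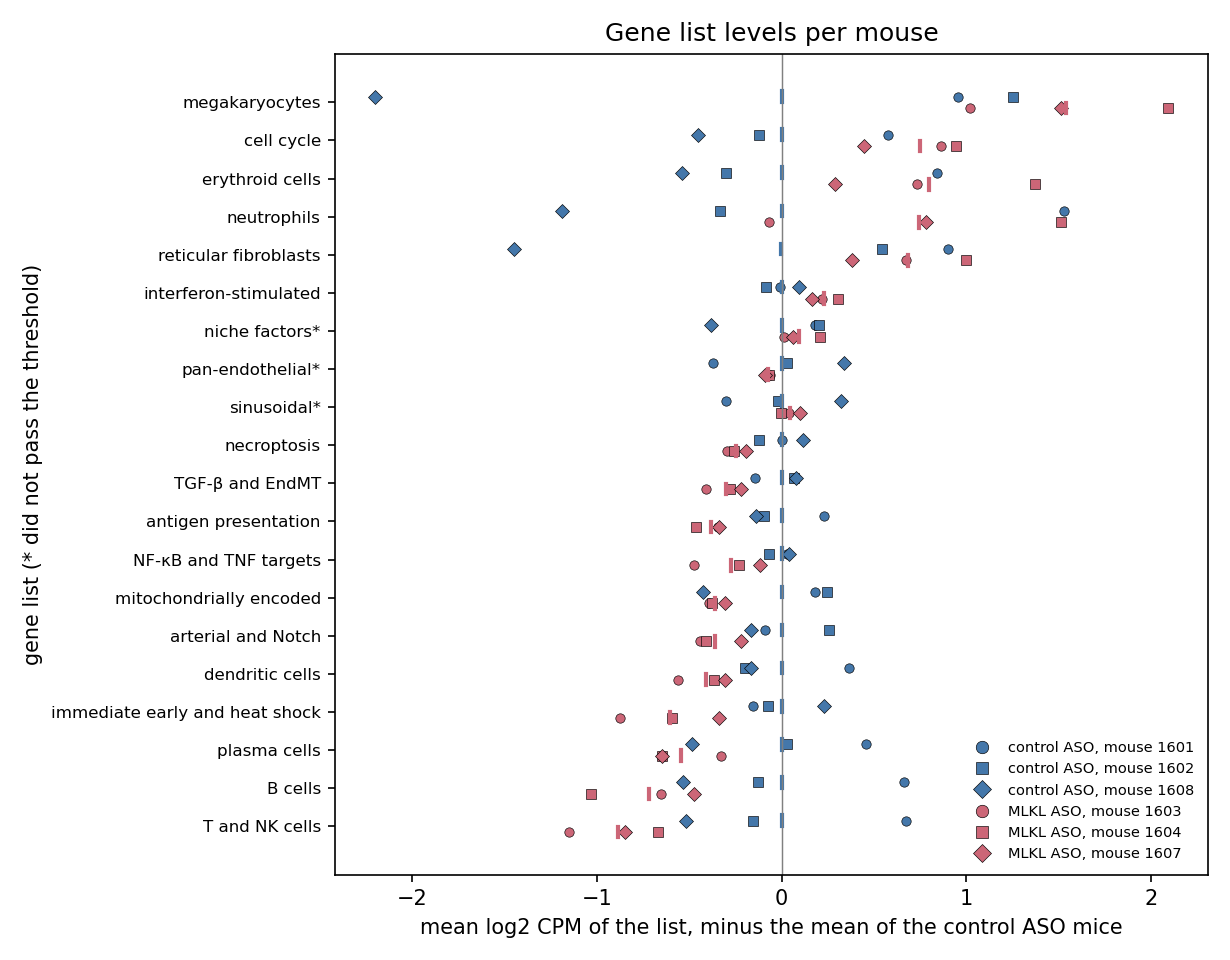
Mean log2 CPM of each gene list per mouse, minus the mean of the 3 control ASO mice, for the 17 lists past the threshold and 3 lists on endothelium and its niche that did not pass (marked with an asterisk). Points are single mice and bars are group means. T and NK cell genes lie lower in each MLKL ASO mouse than in each control mouse, while megakaryocyte genes spread widely within the control group because mouse 1608 lies far below the others.

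Immediate early and stress genes, which cells switch on within minutes of a stimulus, were lower as a list in MLKL ASO mice. The list was fixed beforehand as a quality check for genes induced by tissue dissociation, not as a pathway. Of its 23 members 22 were below 0, with a median log2 fold change of -0.63 (camera adjusted p = 1.89e-14, but adjusted p = 0.427 with an estimated correlation), and 13 passed as lower when adjusted over the list alone. The AP-1 gene Junb measured 1774 ± 345 CPM in control and 691 ± 71.8 CPM in MLKL ASO mice, Ier2 744 ± 77.2 and 419 ± 39.7 CPM, the nuclear receptor Nr4a1 625 ± 162 and 347 ± 46.2 CPM, and the cytokine signalling inhibitor Socs3 76.9 ± 31.1 and 32.2 ± 3.89 CPM. NF-κB and TNF target genes had 21 of 27 members below 0 and a median of -0.36 (camera adjusted p = 0.000264, but adjusted p = 0.427 with an estimated correlation), with 0 past the threshold when adjusted over the list alone. Nfkbia, the inhibitor of NF-κB, measured 959 ± 27.8 and 693 ± 88.8 CPM, and the interferon regulatory factor Irf1 114 ± 22.2 and 71.4 ± 4.63 CPM. Without mouse 1608 the NF-κB median was -0.22. The lymphocyte lists given above had medians below 0 as well.

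The necroptosis list, which holds Mlkl, had 18 of 22 members below 0 and a median log2 fold change of -0.19 (camera adjusted p = 0.00181, but adjusted p = 0.427 with an estimated correlation), and 1 member passed as lower when adjusted over the list alone, which was Mlkl itself. As the MLKL ASO was made to lower Mlkl, part of this call was set by the design: over the other 21 members the median was -0.18 and the list no longer passed camera (camera adjusted p = 0.0503, and adjusted p = 0.583 with an estimated correlation), with 0 past the threshold when adjusted over the list alone. Of these members 17 lay below 0. By fry's directional test they did not pass (fry adjusted p = 0.292), while by its mixed test they passed narrowly (fry adjusted p = 0.049). The adaptor Traf2 measured 89.1 ± 5.63 CPM in control and 69.1 ± 1.06 CPM in MLKL ASO mice, and the death receptor Fas 29.9 ± 2.19 and 22.2 ± 3.04 CPM. The kinases upstream of Mlkl did not separate the groups, with 33.7 ± 8.27 and 34.5 ± 6.78 CPM for Ripk3 (edgeR adjusted p = 0.972) and 25 ± 4.49 and 23.8 ± 2.54 CPM for Ripk1 (edgeR adjusted p = 0.910). With Mlkl among its members the call was lost without mouse 1608 (median -0.14, camera adjusted p = 0.0562).

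Arterial and Notch pathway genes had 19 of 20 members below 0, with a median log2 fold change of -0.39 (camera adjusted p = 0.00189, but adjusted p = 0.427 with an estimated correlation), and 1 passed as lower when adjusted over the list alone. The arterial connexin Gja4 measured 45.5 ± 5.91 CPM in control and 28.3 ± 3.33 CPM in MLKL ASO mice, and the Notch target Hey1 16.0 ± 2.42 and 9.75 ± 1.73 CPM. Genes of TGF-β response and endothelial to mesenchymal transition had 19 of 22 members below 0 and a median of -0.30 (camera adjusted p = 0.00160, but adjusted p = 0.427 with an estimated correlation), with 1 lower when adjusted over the list alone. Among these, Id3, a transcription inhibitor induced by BMP and TGF-β signals, measured 332 ± 40.8 and 179 ± 14.3 CPM. The median of this list was -0.17 without mouse 1608. Antigen presentation genes had 19 of 20 members below 0 and a median of -0.30 (camera adjusted p = 1.52e-05, but adjusted p = 0.427 with an estimated correlation), and 0 passed when adjusted over the list alone. The MHC class II gene H2-Aa measured 1568 ± 737 and 857 ± 109 CPM and the peptide transporter gene Tap2 212 ± 19.4 and 166 ± 9.01 CPM. B cells and dendritic cells also carry MHC class II, and the medians of their lists lay below 0 as well: H2-Aa was highest, at 2387 CPM, in control mouse 1601, which also held the highest levels of B cell and dendritic cell genes. Mitochondrially encoded genes had 13 of 13 members below 0 and a median of -0.38 (camera adjusted p = 0.000655, but adjusted p = 0.622 with an estimated correlation), with 0 past the threshold when adjusted over the list alone, and took 1.92% to 3.17% of the counts in control and 1.82% to 2.19% in MLKL ASO mice, with overlap between the groups. The mitochondrial call was lost without mouse 1602 (median -0.28, camera adjusted p = 0.0618).

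Interferon-stimulated genes were higher as a list, with 23 of 30 members above 0 and a median log2 fold change of 0.18 (camera adjusted p = 0.000217, but adjusted p = 0.427 with an estimated correlation). Adjusted over the list alone, 2 members passed as higher. Rtp4, a chaperone of G protein-coupled receptors, measured 88.9 ± 8.56 CPM in control and 136 ± 2.92 CPM in MLKL ASO mice, and the antiviral gene Ifit3 66.5 ± 3.64 and 96.1 ± 8.40 CPM. The median was 0.27 without mouse 1601, 0.081 without mouse 1602 and 0.32 without mouse 1608.

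Endothelial identity genes did not pass as lists. The list of pan-endothelial genes had 18 of 28 members below 0 and a median log2 fold change of -0.06 (camera adjusted p = 0.273), and the sinusoidal list a median of -0.13 (camera adjusted p = 0.779). The pan-endothelial level (mean log2 CPM) was 6.91, 7.31 and 7.62 in control mice 1601, 1602 and 1608. In MLKL ASO mice it lay between 7.191 and 7.215, inside the range of the controls. Adjusted over the list alone, 1 pan-endothelial gene, Sox17, and 1 sinusoidal gene, Clec4g, were lower, both named here after their values were seen, and DESeq2 called 2 and 1 members lower. The adhesion molecule Pecam1 measured 331 ± 51.6 CPM in control and 362 ± 46.1 CPM in MLKL ASO mice (edgeR adjusted p = 0.784), the junction cadherin Cdh5 166 ± 65.4 and 162 ± 12.5 CPM (edgeR adjusted p = 0.973), and the scavenger receptor Stab2 736 ± 245 and 654 ± 63.7 CPM (edgeR adjusted p = 0.811). Factors that support blood progenitors in their niche did not pass as a list (median -0.06, camera adjusted p = 0.736). The chemokine Cxcl12 measured 145 ± 63.4 and 139 ± 47.9 CPM (edgeR adjusted p = 0.971), stem cell factor Kitl 490 ± 204 and 482 ± 27.4 CPM (edgeR adjusted p = 0.987) and the adhesion molecule Vcam1 359 ± 86.8 and 270.4 ± 58.3 CPM (edgeR adjusted p = 0.518). With controls this spread, a moderate difference in these genes would not have been detectable. Reads of Apoe, the gene knocked out in all mice, were present at 56.4 ± 16.1 and 34.2 ± 3.98 CPM (edgeR adjusted p = 0.342).

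The other lists did not pass either. Among vascular lists, camera adjusted p was 0.0610 for venous genes (median 0.15, mean 0.453), 0.341 for junction genes, 0.353 for basement membrane genes, 0.365 for flow-responsive genes and 0.917 for leukocyte adhesion genes. The venous level (mean log2 CPM) was 0.57 higher in MLKL ASO mice, without overlap between the groups (exact permutation p = 0.1, two-sided, n = 3 per group). Among metabolic and stress lists it was 0.604 for cholesterol synthesis, 0.700 for LXR targets and lipid handling, 0.161 for the unfolded protein response, 0.700 for autophagy and lysosome, 0.232 for glycolysis and 0.365 for nuclear genes of the respiratory chain. Apoptosis genes had 14 of 23 members above 0 (camera adjusted p = 0.0621), ESCRT genes for membrane repair an adjusted p of 0.713 and ribosomal protein genes an adjusted p of 0.779. The apoptosis level was 0.156 higher in MLKL ASO mice, also without overlap (exact permutation p = 0.1, two-sided, n = 3 per group). Among markers of other cells, camera adjusted p was 0.713 for macrophages, 0.779 for stem and progenitor cells, 0.807 for mural cells and 0.128 for mesothelium. The sign of the median differed from that of the mean or of the test for ESCRT, leukocyte adhesion, stem and progenitor and ribosomal genes.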

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

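The edgeR likelihood-ratio test, the removal of globin, immunoglobulin and T cell receptor genes, the erythroid covariate and the removal of Mlkl from the lists were chosen after seeing the data. Mlkl stayed lower under each alternative it was run with, and it was not run with the erythroid covariate. It passed the threshold with DESeq2 (log2 fold change -2.55, adjusted p = 2.07e-15), limma-voom with sample weights (-2.48, adjusted p = 0.0186), the haematopoietic covariate (-2.54, adjusted p = 0.0286), the likelihood-ratio test (-2.55, adjusted p = 8.78e-13) and without globin, immunoglobulin and T cell receptor genes (-2.56, adjusted p = 0.0470). Leaving out a mouse moved it between -2.82 and -2.32, with adjusted p between 0.0571 and 0.322 in edgeR. Against 1 gene higher and 1 lower, edgeR gave 2 and 2 with upper quartile scaling, 30 and 38 with the haematopoietic covariate, 131 and 155 with the likelihood-ratio test, and 4 and 3 without globin, immunoglobulin and T cell receptor genes, DESeq2 gave 237 and 290, and limma-voom with sample weights 9 and 13. Ces2e and Cyp21a1 were among the calls of each of these. Leaving out a mouse gave 0 to 10 genes higher and 0 to 9 lower, most without mouse 1608. The likelihood-ratio and quasi-likelihood tests used the same counts, scaling and genes, so the difference between these counts comes from the test alone. The cause of the other gaps was not tested. In simulated data DESeq2 and the likelihood-ratio test also called more unchanged genes (44 and 36, against 3 by the quasi-likelihood test). The genes called by the authors numbered 669 rows of their deposited table at an adjusted p under 0.1, against 408 at 0.05.

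Of the 6 higher and 11 lower gene lists, 0 and 0 passed with an estimated correlation, and 0 and 0 by fry's directional test. Without Mlkl 5 lists were higher and 10 lower, as the necroptosis list (camera adjusted p = 0.0503) and the reticular fibroblast list no longer passed. The neutrophil median was -0.28 and the reticular fibroblast median -0.32 with the erythroid covariate, and the latter ranged from -0.23 without mouse 1608 to 0.69 without mouse 1601. With that covariate 6 lists were higher, 2 of them shared with the main result, and 9 lower, 8 of them shared. Genes near 0 that changed sign were Cdh5 (0.057 with limma-voom, 0.078 with the haematopoietic covariate, -0.30 to 0.30 on leaving out a mouse), Kitl (0.12, 0.10, and -0.28 to 0.36), Ripk3 (-0.10 to 0.23), Ripk1 (-0.20 to 0.077), Stab2 (-0.39 to 0.12) and Cxcl12 (-0.38 to 0.20). Prtn3, at 0.84 with all mice, went from -0.046 without mouse 1604 to 2.10 without mouse 1601. The cause of these changes was not tested. No paired analysis was possible because no mouse number occurs in both groups.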

Other observations

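The genes in this paragraph and the next were chosen after their values were seen, and 0 of them passed the threshold in edgeR. The splits of the mice and the test of erythroid cells for Ces2e, Inka2, Eda2r and Zmat3 were set before their results were seen, and the other tests below only after the pattern had been noticed. Endothelial genes outside the naming rule included Sox17, a transcription factor of arterial endothelium, with 205 ± 49.3 CPM in control and 78.1 ± 4.68 CPM in MLKL ASO mice (edgeR adjusted p = 0.121). Clec4g, a lectin of sinusoidal endothelium, measured 406 ± 52.0 and 185 ± 27.4 CPM (edgeR adjusted p = 0.121), and Pdgfb, the growth factor that recruits pericytes, 16.0 ± 1.44 and 8.85 ± 0.158 CPM (edgeR adjusted p = 0.183). Higher in MLKL ASO mice were Ackr1, a chemokine scavenger of venules, at 13.2 ± 5.57 and 38.0 ± 7.55 CPM (edgeR adjusted p = 0.270), and the fatty acid binding protein Fabp4 at 77.9 ± 17.1 and 158 ± 12.4 CPM (edgeR adjusted p = 0.183). Masp1, a protease of the lectin complement pathway, measured 2.88, 3.45 and 11.1 CPM in control mice 1601, 1602 and 1608 and between 75.5 and 79.3 CPM in the MLKL ASO mice (edgeR adjusted p = 0.126). In the authors' deposited table Sox17 (log2 fold change -1.38), Clec4g (-1.12) and Masp1 (3.74) are past the threshold, with adjusted p of 4.3e-06, 2.19e-05 and 2.11e-12.

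Of the steroidogenic genes other than Cyp21a1, Star, which carries cholesterol into mitochondria, measured 3105 ± 1200 CPM in control and 2918 ± 255 CPM in MLKL ASO mice (edgeR adjusted p = 0.928), and the regulator Nr5a1 98.7 ± 43.6 and 88.3 ± 1.78 CPM (edgeR adjusted p = 0.863). Cyp11a1, the side-chain cleavage enzyme, measured 2.36 ± 1.20 and 0.992 ± 0.597 CPM with overlap between the groups (edgeR adjusted p = 0.437), and the receptor gene Lhcgr 0.245 ± 0.108 and 0.0305 ± 0.0145 CPM without overlap (edgeR adjusted p = 0.294), which the authors' deposited table places past the threshold (log2 fold change -4.58, adjusted p = 0.000417). The chemokine copy Ccl21d was at 0 in the control mice and at 5.28, 26.7 and 16.3 CPM in mice 1603, 1604 and 1607, but the sum over Ccl21a, Ccl21b and Ccl21d, near-identical copies between which Salmon divides reads, was 201 ± 84.7 and 278 ± 113 CPM (exact permutation p = 0.5, two-sided, n = 3 per group).

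Ces2e, which passed the threshold, and Inka2, Eda2r and Zmat3, which did not, are known targets of the tumour suppressor p53, and each was higher in every MLKL ASO mouse than in every control mouse. Eda2r measured 2.07 ± 1 CPM in control and 14.97 ± 2.26 CPM in MLKL ASO mice (edgeR adjusted p = 0.109), Inka2 1.04 ± 0.194 and 5.97 ± 0.546 CPM (edgeR adjusted p = 0.0566), and Zmat3 3.39 ± 0.204 and 9.07 ± 1.62 CPM (edgeR adjusted p = 0.145). A candidate explanation is that p53 targets were higher as a group: of 37 other targets, listed after this pattern had been noticed, 34 were measured and 26 lay above 0 (at an unadjusted p under 0.05, 11 were higher and 2, Btg2 and Fas, lower), with a median log2 fold change of 0.36 and a camera p of 9.12e-07 with the preset and p = 0.00479 with an estimated correlation, and the 23 of them in no other list gave p = 0.00495 with an estimated correlation. The list held 30 targets at its first test (p = 0.00529 with an estimated correlation) and 34 at the next (p = 0.00564), as 7 left out after values had been seen were put back. These camera p-values are unadjusted, as the list was tested alone, whereas those of the lists fixed beforehand are adjusted over 38 lists. Of the fixed lists, 3 had an unadjusted p under 0.05 with an estimated correlation and 0 passed once adjusted. Over the 10 splits of the mice into 3 and 3 the smallest other p was 0.233. The list was prompted by genes that separate the labelled grouping, so a small p in that split was favoured from the start. Besides, 10 splits are too few for a share under 0.05. The p53 targets Ckap2 (log2 fold change 1.16), Psrc1 (1.095) and Gtse1 (0.87), which are in no other list, also act in cell division. The cell cycle list was higher too, and how much of the p53 target difference follows proliferation was not tested. With the erythroid level as a covariate the median of the measured targets was 0.39. Erythroid cells are argued against as the source of the 4 genes, whose median was 2.48 without and 2.48 with the erythroid level as a covariate, but each group received 1 kind of oligonucleotide, so the sequence or chemistry of the MLKL ASO and the loss of Mlkl cannot be told apart.

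By camera at the preset correlation the lymphocyte lists were lower and the erythroid, megakaryocyte and cell cycle lists higher, but with an estimated correlation their adjusted p was 0.427 for T and NK cell, B cell, plasma cell and cell cycle genes and 0.525 for erythroid and megakaryocyte genes. A single change in the endothelial share of the cells would have moved all blood cell markers in the same direction, but the erythroid level minus the T and NK cell level differed by 1.68 (log2) between the groups, against SDs of 0.16 and 0.482, without overlap. Cycling erythroid precursors may account for much of the cell cycle difference: with the erythroid level as a covariate the median of that list went from 0.78 to 0.24, though camera at the preset correlation still placed it past the threshold (adjusted p = 0.000123). Whether the mixture of cells differed through the treatment or through the preparation of the cells stays open, as neither was tested, and the control mice differ widely in the same markers.

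The immediate early and stress list was lower by camera at the preset correlation (adjusted p = 0.427 with an estimated correlation), and all 16 immediate early members lay below 0, with a median log2 fold change of -0.75. Fewer lymphocytes are argued against, though not ruled out, as the whole cause: with the level of lymphocyte markers as a covariate the median was -0.89 (median SE 0.285 per gene), and control mouse 1608, with Trbc2 at 34.9 CPM, had Junb at 1935 CPM. The T and NK cell level did not overlap between the groups, so with 6 mice the lymphocyte covariate cannot be fully separated from the treatment. Handling or dissociation stress that differed between the groups cannot be told apart from the treatment. The 7 heat shock members of the list had a median of -0.37, lower in 6 of 7, a difference smaller than that of the immediate early genes by more than the SD of the latter (0.284) and yet below 0.

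Regrouping the mice gave 10 splits into 3 and 3, too few for a share under 0.05. In edgeR 1 split, the real one, gave as many as its 2 genes, and the highest other count was 1. With DESeq2 the real split gave 527 genes, reached by 1 of 10 splits, and the highest other count was 119. For gene lists by camera at the preset correlation, 4 of the 10 splits gave at least the 17 of the real grouping, and the highest other count was 21, so the libraries hold structure in these lists that does not follow the treatment.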
